A study of Mus musculus with 2 samples.

How the data were processed

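Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in colonic macrophages sorted as Siglec-F-negative, Ly6C-low and CD64-positive cells from male C57BL/6 mice aged 18.9 weeks. The libraries comprised 1 from WT mice (Lyz2-Cre) and 1 from mice with Tle4 deleted in myeloid cells (Tle4f/f Lyz2-Cre, called Tle4cKO). Each library was made from the cells of 2 mice, pooled by genotype and sorted at the same time, per the labels' protocols.

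The authors deposited 1 peak list per library, called separately for each. Each row holds a position, a width, a summit and the pileup at the summit. The deposited pileup is a signal in whole numbers from 7 upwards, per the file headers and values, and the width equals end minus start plus 1, so that coordinates count from 1 and include both ends. The submitters' processing notes name cutadapt 1.14, Bowtie2 2.2.5, MACS2 2.1.1, featureCounts 1.5.0, edgeR 3.28.1, HOMER 4.7.2 and the build mm10, without their roles or order. Calling thresholds, shifting of reads for the transposase, duplicate handling, read totals and any scaling between libraries are not given in the sources used here. The pileup is the authors' own value per peak. It was used to describe, rank and filter peaks within a list. Ratios of single pairs are given as raw values and were read against peak pairs of like pileup from the same lists.

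Peaks were counted as shared when they overlapped a peak of the other list by at least 1 bp, and otherwise as WT-only or Tle4cKO-only; the counts were checked with bedtools 2.31.1. Strong peaks were those at or above the upper quartile of pileup in their own list. Lists of equal length held the 20000 peaks with the highest pileup. Peaks that were each other's highest overlapping peak formed 92328 reciprocal pairs. In each pair the WT and Tle4cKO pileups were given percentile ranks within this common set, and the shift is the Tle4cKO percentile minus the WT percentile. The log2 ratio of the pileups was also expressed relative to the median of its bin among 50 bins of summed pileup. Shares have 95% Wilson intervals and pileup ratios exact Clopper-Pearson intervals. Both cover counting error only, and a summit pileup is a maximum over a peak, for which such an interval is approximate. With 1 library per genotype, no SD, SE or p-value between genotypes was computed, and every difference describes these libraries without a replicate check.

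Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10. It gives the ends of each gene and neither strand nor exons. The promoter classes set in the design were therefore replaced by the interval within 1000 bp of either annotated gene end, gene body and outside genes. Motif content was not analysed here, since no genome sequence was used. The planned ranking by fold enrichment was replaced by ranking by pileup, the value the lists hold. Read counts per region were not used here.

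For 28 gene lists with 418 genes, all of which matched the table, peaks within the gene and 10 kb on either side were counted. The balance of a list is its Tle4cKO-only minus its WT-only peaks. The balance and the median shift of the pairs were each given a percentile among 10000 random gene lists matched on peak number in 10 bins and on mean percentile rank in 3 bins. These percentiles describe the libraries and are not p-values. The gene lists, the overlap rule, the ranking by strength, the lists of equal length and the alternatives not named below as added were chosen before the data were examined. The pairs, the percentile shift, the matching on mean percentile rank, the 2-Mb windows, the distal X segment and the pileup minimums of 15 and 20 were added afterwards.

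Named genes were the TLE family; up to 4 members per list with the largest difference between Tle4cKO-only and WT-only peaks; Il10, Mmp9, Cx3cr1, Csf1r, Spi1, Il1b, Tnf, Mrc1, Il10ra, Axin2 and Hes1; the genes whose span was nearest to the 10 strongest peaks of each list-only set on assembled chromosomes; and the 5 genes with the most WT-only and the 5 with the most Tle4cKO-only peaks. Predicted genes were skipped, and some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen. The distal X segment was the run of 0.5-Mb bins with at least 5 pairs and a median relative log2 ratio of -0.3 or lower. The start of the drop within its first bin was placed by a least-squares split of the same ratios.

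The steps were tested on simulated data. The WT list of 128737 peaks was thinned by Poisson draws to the Tle4cKO pileup. From it 200 of 200 planted WT-only and 200 of 200 planted Tle4cKO-only peaks were recovered. Peak positions were kept, so this recovery was fixed in advance and did not test shifted borders, splitting or calling. Of 200 pairs raised 2-fold, 198 had an interval above the ratio of pairs of like pileup. Of 200 pairs lowered 2-fold, 186 had one below it, against 0.461% of unchanged pairs outside it in either direction. The changed pairs were drawn from WT peaks with a pileup of at least 40 and under 200, above the WT median of 28. Recovery of changes in weaker pairs was therefore not tested. A list of 20 genes, each with its balance raised by 2, reached the 99.9th percentile, while 1 of 40 random lists fell outside the central 95%. The balance itself was raised, so peak counting was not tested, and fewer random lists were drawn than in the main analysis. A planted shift of 5 points reached the 100th percentile, and 1 of 10 random lists fell outside. Alternatives covered the overlap rule, strength thresholds, merging of peaks, sequences used, list length, gene-end window and gene flank. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.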

Results

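Accessible chromatin was profiled by ATAC-seq in sorted colonic macrophages from WT mice and from mice lacking Tle4, a Groucho-type transcriptional corepressor, in myeloid cells. The comparison asks which accessible regions differ between the genotypes. The data comprised 1 library per genotype, each from 2 pooled male mice, so that no value below has a replicate check. The WT list held 128737 peaks and the Tle4cKO list 128129 peaks. The median pileup was 28 in WT and 20 in Tle4cKO, and the highest on assembled chromosomes was 314 and 273. Read totals were not given in the sources used here, and no scaling between the libraries is recorded.

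At the Tle4 locus itself the WT list held more peaks than the Tle4cKO list. Within the gene (chromosome 19, 14448072 to 14598183, mm10) and 10 kb on either side lay 22 WT and 14 Tle4cKO peaks, of which 12 were WT-only and 3 Tle4cKO-only. The WT-only peaks had pileups of 8 to 29, the highest at 14588191 to 14588736 inside the gene, and the Tle4cKO-only peaks each had a pileup of 8. The balance of -9 was at the 1.70th percentile of 501 genes with 32 to 40 peaks in both lists together. Those genes were matched on peak number and not on pileup, and weak peaks are often in 1 list only. The 10 pairs at Tle4 had a mean percentile rank of 38.0 and a median shift of -1.07 percentile points. Their median relative log2 ratio was -0.027. The strongest peak of the locus, across a gene end at 14596847 to 14599206, was kept, with a pileup of 238 in WT and 220 in Tle4cKO. Their ratio was 0.924 (95% interval 0.766 to 1.12). The median ratio of pairs in the highest of 10 classes of summed pileup, 0.814, lies within that interval. The next strongest, inside the gene at 14585178 to 14586679, had pileups of 109 and 92. The labels do not locate the deleted part of the gene, so these peaks do not check the genotype.

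**Figure D1:**
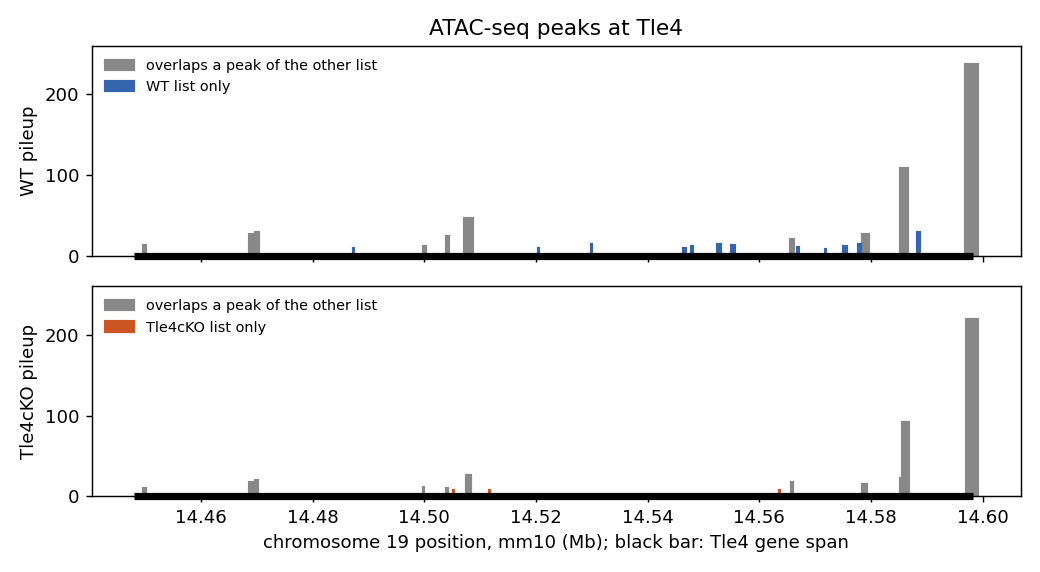
ATAC-seq peaks at Tle4 in the WT list (top) and the Tle4cKO list (bottom), with position on chromosome 19 in Mb on the x axis and pileup on the y axis; grey peaks overlap a peak of the other list, coloured peaks do not, outlines widen the narrowest peaks, and the black bar is the gene span. The gene-end peak reaches 238 and 220, and the 12 WT-only peaks have pileups of up to 29.

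Of the other TLE family genes, Tle3 held 6 Tle4cKO-only and 4 WT-only peaks, and Tle1 held 2 and 5. Tle2, Tle5 and Tle6, which lie together on chromosome 10, each held 1 WT-only and 0 Tle4cKO-only peaks, and their flanks overlap. The family's balance of -13, with Tle4 included, was at the 7.73rd percentile of matched random lists.

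The libraries shared most of their accessible regions. Of the WT peaks, 72.9% (95% interval 72.7% to 73.2%) overlapped a Tle4cKO peak, and 76.5% (76.3% to 76.8%) of the Tle4cKO peaks overlapped a WT peak. This left 34872 WT-only and 30079 Tle4cKO-only peaks. WT peaks had a median width of 671 bp and covered 101 Mb, and Tle4cKO peaks had a median width of 604 bp and covered 89.2 Mb. Peaks found in 1 list were weak, with a median pileup of 12 in the WT-only set and 10 in the Tle4cKO-only set, against 43 and 28 in the shared sets. Of the 12874 WT peaks with the lowest pileup, 84.0% (83.4% to 84.7%) were WT-only, and of the 12874 with the highest, 1 was. In the Tle4cKO list 81.0% (80.3% to 81.6%) of the 12813 lowest peaks were Tle4cKO-only, and 1 of the 12813 highest.

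**Figure D2:**
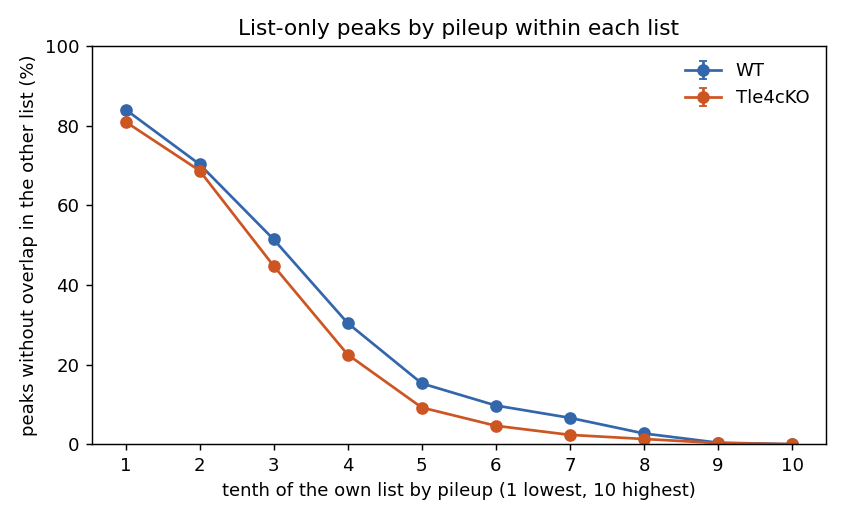
Share of peaks without overlap in the other list (y axis, %) by rank class of pileup in the own list (x axis, 10 classes of equal size, 1 lowest), for WT (blue) and Tle4cKO (orange), with 95% Wilson intervals smaller than the points. The share falls from 84.0% and 81.0% in the lowest class to 1 peak in the highest class of each list.

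Among strong peaks, few were missing from the other genotype. Of 32410 WT peaks with a pileup of at least 67, 168 (0.518%, 0.446% to 0.603%) were WT-only, and of 32618 Tle4cKO peaks with a pileup of at least 47, 102 (0.313%, 0.258% to 0.379%) were Tle4cKO-only. The strongest WT-only peaks lay at the MHC class II genes, which present antigen to CD4 T cells. A peak of pileup 135 (chromosome 17, 34291506 to 34291724) and one of 125 (34291873 to 34292088) lay 3683 and 4050 bp from H2-Aa. One of 111 (34307116 to 34307329) lay in H2-Eb1. These peaks lay 1479, 1115 and 177 bp from the nearest Tle4cKO peak, so the last counts as shared within 500 bp. H2-Eb1 also held the second strongest Tle4cKO-only peak, with a pileup of 89 (34309505 to 34309856). The strongest Tle4cKO-only peak, with a pileup of 99, and the eighth, with 77, lay in Sfi1 on chromosome 11. The latter lay 439 bp from a WT peak. The shared peaks at Sfi1 also ranked higher in Tle4cKO, with a median shift of 10.3 percentile points over 12 pairs. Other strong WT-only peaks lay in Atp6v0c (110), Srgn (109), Tcof1 (109), Sin3a (105) and Tspoap1 (103), and outside genes nearest to Fgd2 (109) and Frmd8 (105). Other strong Tle4cKO-only peaks lay in Efhd2 (76), and outside genes nearest to Lrrc25 (88), Frmd8 (86), Kcnrg (79), Vmp1 (77) and Klf14 (76), the last at 153801 bp. The strong list-only peaks had a median width of 266 bp in WT and 238 bp in Tle4cKO. Their median distance to the nearest peak of the other list was 813 bp and 547 bp. Among the 10 strongest of each set, 2 of WT and 3 of Tle4cKO lay within 500 bp of such a peak. Of the 168 and the 102, 50 and 45 lay within 500 bp of a peak of the other list. Counting those as shared left 118 and 57.

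When the 20000 strongest peaks of each list were set side by side, 93.2% (92.8% to 93.5%) of the WT and 94.0% (93.7% to 94.3%) of the Tle4cKO peaks overlapped the other top list. Of these top peaks, 13 of WT and 13 of Tle4cKO overlapped no peak in the whole other list. Among the 10000 strongest that count was 0 and 0, and among the 40000 strongest it was 457 and 228.

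Shared peaks lay at gene ends more often than list-only peaks did. Within 1000 bp of an annotated end of a protein-coding gene lay 16.6% (16.3% to 16.8%) of shared WT peaks and 5.80% (5.56% to 6.05%) of WT-only peaks. In the Tle4cKO list these shares were 16.2% (16.0% to 16.4%) and 5.13% (4.89% to 5.39%). Any overlap with the interval counted, and shared peaks were wider. Their median width was 809 bp in WT and 709 bp in Tle4cKO, against 322 bp and 267 bp for list-only peaks. The shares were not matched on width. Gene bodies held 53.5% of WT-only and 51.5% of Tle4cKO-only peaks. Among strong peaks in the same 1000 bp, 32.6% of shared WT peaks and 11.9% (7.84% to 17.7%) of WT-only peaks lay at gene ends, against 32.4% and 10.8% (6.13% to 18.3%) in Tle4cKO. Within 2500 bp, the difference among strong peaks was within the intervals, with 39.1% of shared and 39.9% (32.8% to 47.4%) of WT-only peaks, and 39.2% of shared and 33.3% (24.9% to 42.9%) of Tle4cKO-only peaks.

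The heights of shared peaks followed each other closely. Over 92328 pairs the median Tle4cKO to WT pileup ratio was 0.741, and the pileup was higher in WT in 90.8% of pairs. Across pairs, which are not independent replicates, the Spearman correlation was 0.962. The counting interval lay above the ratio of pairs of like pileup in 631 pairs and below it in 568 pairs, together 1.30% of pairs. That share lies between the 0.461% of unchanged pairs outside in the simulated thinning, where 1 list alone carried counting error, and the 5% that such intervals place outside at most for independent counts without a difference. The SD of the relative log2 ratio was below that of Poisson counts in all 10 classes of summed pileup, with 0.102 against 0.164 in the highest.

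Genes that mark intestinal macrophages kept their gene-end peaks in both libraries. All 22 identity genes and all 20 macrophage transcription factor genes had a gene-end peak in each list. Csf1r, the receptor for the growth factor CSF-1, held 3 Tle4cKO-only and 0 WT-only peaks, the highest with a pileup of 53 (chromosome 18, 61096607 to 61096817). Cx3cr1, the fractalkine receptor, held 2 WT-only peaks with pileups of 38 and 42 and 0 Tle4cKO-only peaks, Timd4 held 3 WT-only peaks and Cd81 held 2. Over the identity list, 11 genes had more WT-only and 4 more Tle4cKO-only peaks, with a balance of -12 at the 43.5th percentile. Its median shift was -0.52 percentile points, at the 2.97th percentile. Among the transcription factors, Runx1 held 18 WT-only and 12 Tle4cKO-only peaks, Tcf4 9 and 3, Nr4a1 4 and 0, and Batf3 3 and 0, while Spi1, which encodes PU.1, held 3 and 2. That list's balance of -23 was at the 18.5th percentile.

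The 22 genes of the anti-inflammatory and IL-10 list held 41 Tle4cKO-only and 37 WT-only peaks, and the balance of 4, at the 93.7th percentile, lay within the central 95% of random lists. It was at the 74.7th percentile with 50 kb on either side, at the 24.3rd with strong list-only peaks and at the 97.7th with peaks within 500 bp counted as shared. The median shift of shared peaks, a statistic chosen after the data were seen, was 1.05 percentile points over 226 pairs, at the 98.2nd percentile. The monocyte, neutrophil and B and plasma cell marker lists lay on the same side of this statistic, at the 98.7th, 99.3rd and 97.6th percentiles. Over all 28 lists and both statistics, 5 of 56 values lay outside the central 95%, where 2.8 would by construction. Mrc1, which encodes the mannose receptor CD206, supplied 33 of the 226 pairs, with a median shift of 4.7, although it held 10 WT-only and 4 Tle4cKO-only peaks. Il10 held 3 Tle4cKO-only peaks with pileups of 13, 15 and 19 and 0 WT-only peaks. Its median shift was -0.697 over 7 pairs, and its peak at 131020762 to 131022043 on chromosome 1 had pileups of 165 in WT and 133 in Tle4cKO. Smad3 held 9 Tle4cKO-only and 6 WT-only peaks, Etv3 2 and 0, and Il10ra 1 and 2.

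Pro-inflammatory genes lay near the middle of the random lists. The pro-inflammatory list had 28 WT-only and 24 Tle4cKO-only peaks, with a balance at the 74.2nd percentile and a median shift of 0.105. Nfkb1, a subunit of NF-kappaB, held 8 Tle4cKO-only and 4 WT-only peaks. Il1b held 3 WT-only peaks with pileups of 26, 29 and 30 and 0 Tle4cKO-only peaks, Ccl5 3 and 0, Ptgs2 2 and 0, and Tnf 1 and 0. In the interferon response list, 10 of 18 genes had more WT-only peaks, and the balance of -15 was at the 18.9th percentile. Ifih1, which encodes the RNA sensor MDA5, held 8 WT-only and 0 Tle4cKO-only peaks, all with pileups of at most 14, Gbp2 3 and 0, Ifnb1 3 and 1, and Ifit2 1 and 4. Matrix metalloproteinase genes had 23 Tle4cKO-only and 22 WT-only peaks (78.9th percentile): Mmp9 held 1 Tle4cKO-only peak of pileup 17, Mmp17 3 against 1 WT-only, Mmp16 4 against 2, Mmp12 3 against 4 and Timp2 2 against 5.

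Antigen presentation genes had 32 WT-only and 15 Tle4cKO-only peaks (18.6th percentile), with 8 and 3 at Cd86, 5 and 1 at Cd80, 2 and 0 at H2-Aa, and 2 and 0 at H2-D1. When strong list-only peaks alone were counted, this list's balance was -4, at the 0.265th percentile. That of the macrophage transcription factors was -7, at the 0th percentile. The random lists were not matched on the number of strong peaks, and strong list-only peaks were more frequent in WT, 168 against 102. These percentiles may therefore follow from how many strong peaks the lists hold, which was not tested. Phagocytosis genes had 81 WT-only and 57 Tle4cKO-only peaks (22.1st percentile), with 17 and 9 at Elmo1, 7 and 2 at Abcg1, 4 and 0 at Fcgr3, and 9 and 6 at Cd36. Lipid metabolism genes had 36 and 27 (57.5th percentile), with 5 and 0 at Plin2, 5 and 1 at Lipa, and 2 and 5 at Npc1.

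Of the signalling and transcription lists, AP-1 was outside the central 95% of random lists. For the balance it was the 1 such list of all 28, where 5% of lists would lie outside by construction. Its 12 genes held 12 Tle4cKO-only and 5 WT-only peaks, a balance of 7 at the 98.2nd percentile. Fosl2 held 5 Tle4cKO-only and 1 WT-only peaks and Atf3 4 and 1, while the other 10 genes were balanced. With 50 kb on either side the balance was 3, at the 94.8th percentile, and with strong list-only peaks it was 1, at the 93.5th. Wnt genes had 36 WT-only and 33 Tle4cKO-only peaks (72.4th percentile), with 10 and 3 at Lrp6, 1 and 5 at Lef1, 3 and 0 at Ctnnb1, 3 and 0 at Fzd4, and 1 and 2 at Axin2. Notch and HES genes had 34 and 32 (73.0th percentile), with 8 and 2 at Rbpj, 14 and 16 at Notch2, 0 and 2 at Jag2, 2 and 3 at Notch1, and 0 and 1 at Hes1. Clock genes had 31 and 19 (27.2nd percentile), with 5 and 0 at Clock, 4 and 1 at Cry1, 3 and 0 at Nr1d2, and 2 and 0 at Nr1d1.

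Markers of other cell types were also compared. The gate selects against eosinophils by Siglec-F, against monocytes by Ly6C and against cells without CD64, among them lymphocytes, epithelium and stroma. The balances of all 12 such lists lay within the central 95%: monocyte -6 (40.7th percentile), neutrophil -4 (34.6th), eosinophil -2 (36.8th), mast cell 1 (60.7th), dendritic cell 1 (84.6th), T cell 2 (80.9th), B and plasma cell 2 (80.3rd), NK and ILC -6 (25.6th), colon epithelium -6 (29.2nd), fibroblast and muscle -2 (49.3rd), endothelium -10 (19.97th) and enteric neuron and glia -4 (18.6th). The median shift of shared peaks was outside that range towards Tle4cKO for monocyte genes (2.41 points, 98.7th percentile), neutrophil genes (3.33, 99.3rd) and B and plasma cell genes (1.78, 97.6th). These lists had 55, 33 and 71 pairs. Gene-end peaks were found at 8 monocyte, 7 neutrophil and 13 B and plasma cell genes in WT, and at 7, 5 and 12 in Tle4cKO. Fn1 held 4 Tle4cKO-only and 0 WT-only peaks, F13a1 1 and 4, Vcan 0 and 4, Ly6c2 0 and 3, and Chil3 belongs to both the monocyte and the anti-inflammatory list. Cxcr2, Retnlg and Ltf had WT-only peaks and 0 Tle4cKO-only peaks, and Ngp held 4 Tle4cKO-only and 1 WT-only. Pax5 held 8 Tle4cKO-only and 4 WT-only, Ebf1 8 and 6, Cd247 6 and 1, and Kit 7 and 3. Krt8 held 6 WT-only and 1 Tle4cKO-only, Muc2 0 and 3, Pecam1 5 and 1, and Pdgfrb 2 and 0. Housekeeping genes had a gene-end peak for all 15 members in both lists and a balance of -5 (46.5th percentile). Of the 20 genes expected to be silent, 6 had a gene-end peak in each list, with a balance of -3 (26.1st).

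**Figure D3:**
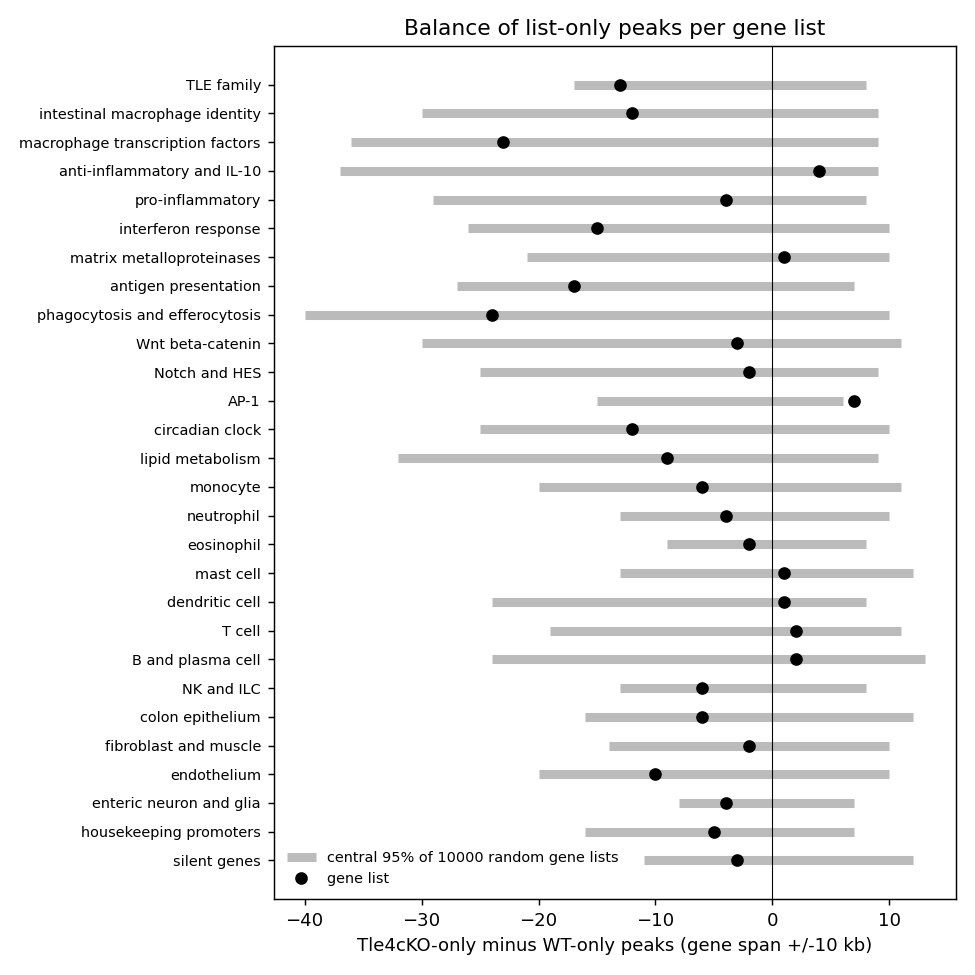
Tle4cKO-only minus WT-only peaks in the gene and 10 kb on either side (x axis) for each gene list (y axis), as black points over the central 95% of 10000 matched random gene lists (grey). The AP-1 list, at 7, is outside the grey range.

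The gene with the most WT-only peaks was Arhgap6 on the X chromosome, which encodes a GTPase-activating protein. Its 72 WT peaks included 47 WT-only peaks, and its 27 Tle4cKO peaks included 0 Tle4cKO-only ones. Next came Pde4d with 41 WT-only and 22 Tle4cKO-only peaks, Mpp7 with 38 and 20, Arhgap26 with 37 and 23 and Vav3 with 37 and 21. The genes with the most Tle4cKO-only peaks were Macrod2 (40, beside 27 WT-only), Xylt1 (33 and 29), Fndc3b (30 and 18), Cdh23 (28 and 18) and Snd1 (28 and 27).

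Arhgap6 lay in a distal segment of the X chromosome, 166.5 to 170 Mb, in which the libraries differed over many neighbouring peaks. In it 110 of 237 WT peaks were WT-only (46.4%, 40.2% to 52.8%), and 2 of 140 Tle4cKO peaks were Tle4cKO-only (1.43%, 0.393% to 5.06%). On the rest of X, 29.2% of WT peaks were WT-only and 8.0% of Tle4cKO peaks were Tle4cKO-only. Of the segment's 127 pairs, 120 (94.5%) lay below the ratio of pairs of like pileup, with a median relative log2 ratio of -0.57. The WT pileup was thus 1.48-fold higher relative to pairs of like pileup. The first 12 pairs, up to 166765347, had a median of -0.10 and held 5 of the 7 pairs not below that ratio, although 3 of the 12 lay below the median of the segment. A least-squares split of the relative log2 ratios in the first 0.5 Mb placed the start of the drop at the pair at 166899174. From there on 113 of 115 pairs lay below the ratio of pairs of like pileup, which follows in part from that split. No pair started between 167497644 and 168639361. On the rest of X the median was -0.04. The windows at 166 to 168 and 168 to 170 Mb had the lowest medians of 1095 windows of 2 Mb, -0.53 and -0.56. The segment, chosen after its values were seen, also holds Tlr7 and Tlr8, which encode endosomal RNA sensors and had median shifts of -16.1 over 9 pairs and -19.0 over 4 pairs. Leaving it out gave 72.9% and 76.5% of peaks shared.

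**Figure D4:**
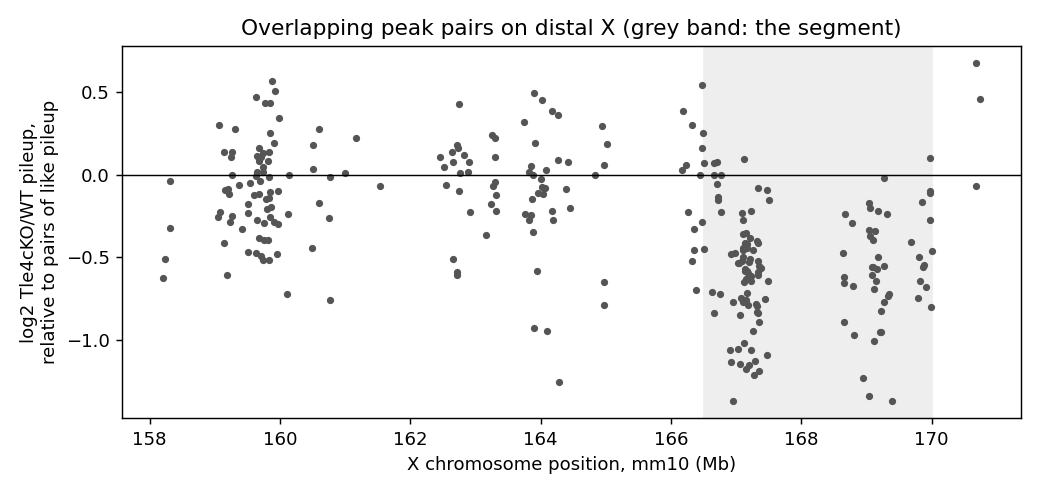
Relative log2 ratio of Tle4cKO to WT pileup (y axis) of each reciprocal peak pair by position on the distal part of the X chromosome in Mb (x axis); the grey band is the segment from 166.5 to 170 Mb and the line at 0 is the median of pairs of like pileup. Of the 127 pairs in the band, 120 lie below the line.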

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

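The tests with own peaks of pileup 20 or more, without the distal X segment and with the median shift in place of the balance were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library, and for the same reason no replicate could be left out. A q-value threshold and ranking by q were not run, since the lists used here give no q, and both motif alternatives were not run without a genome sequence. The shared share of WT and Tle4cKO peaks was 60.6% and 60.9% with 50% reciprocal overlap, 68.9% and 74.0% with the summit inside a peak of the other list, and 76.9% and 80.0% within 500 bp. It was 89.7% and 92.6% for the stronger 50% of both lists, 96.2% and 98.4% for the stronger 50% of the own list against the whole other list, and 93.6% and 98.2% for own peaks of pileup 20 or more. Restricting to stronger peaks removes the weak ones that make up most list-only peaks. Merging within 150 bp gave 73.5% for WT. Merging adjacent peaks, autosomes and X alone, and leaving out the distal X segment kept both shares within their intervals, as merging within 150 bp did for Tle4cKO. Strong Tle4cKO-only peaks numbered 57 when peaks within 500 bp counted as shared. Absent top peaks numbered 0 in both lists at 10000 peaks, and 457 of WT and 228 of Tle4cKO at 40000. With gene ends of 2500 bp, 22.8% and 22.7% of shared and 11.97% and 10.7% of list-only peaks lay there, while strong peaks within 1000 bp gave 32.6% and 32.4% against 11.9% and 10.8%. For strong peaks within 2500 bp these shares were 39.1% and 39.2% against 39.9% and 33.3%. The number of gene lists outside the central 95%, 1 in the main setting, was 0 with 50 kb on either side, 2 with strong list-only peaks, 2 with 500 bp counted as shared and 4 with the median shift. For these gene list counts and overlap rules the cause was not tested. Over the gene lists one by one, 107 values stayed on their side of the central 95%, 3 moved outside it and 2 moved inside, both of AP-1. Most peaks with a pileup near the minimum of 7 were in 1 list, and how far depth limits their comparison was not tested, since read totals are not given in the sources used here.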

Other observations

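The tests on the distal X segment were chosen after the result was seen, as was the chromosome 19 window, while the tests on that window and on strong list-only peaks were set before the values they measure were seen.

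Several genes outside the naming rule stood apart in the height of their shared peaks and were chosen after their values were seen. Of 8943 genes with at least 4 pairs, 37 had a median shift above 10 percentile points towards Tle4cKO and 33 had one below -10. Hsph1, which encodes a large heat shock protein, had a shift of 18.5 over 7 pairs. Its strongest pair, with pileups of 247 in WT and 209 in Tle4cKO, stayed at the 99.9th and 99.8th percentiles, so the shift came from weaker pairs. The neighbouring Wdr95 had 21.8 over 9 pairs, with 12 Tle4cKO-only and 2 WT-only peaks, and the flanks of Hsph1 and Wdr95 overlap. Trpm8, an ion channel gene, had 19.1 over 6 pairs. At Stac, a peak at 111677168 to 111677584 on chromosome 9 had a pileup of 12 in WT and 43 in Tle4cKO (ratio 3.58, 95% interval 1.86 to 7.46). Another at 111603771 to 111604318 had 16 and 54 (3.38, 1.90 to 6.32). Relative to pairs of like pileup, their log2 ratios were 2.43 and 2.31. In the other direction, Mmp13, which encodes collagenase 3, had -18.3 over 6 pairs and Pla2g2d -17.6 over 7 pairs. A peak in Gfra3 (chromosome 18, 34705960 to 34706971) had 50 in WT and 11 in Tle4cKO (ratio 0.22, 0.103 to 0.428). Its log2 ratio relative to pairs of like pileup was -1.62. These are extremes picked from many genes and pairs in 1 library per genotype.

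The Tle4cKO pileup on the distal X segment lay below that of pairs of like pileup in 113 of the 115 pairs from 166899174 on. That start was set by a split of the same ratios, so the count restates in part how it was chosen. A drop over the whole of X as large as that in the segment is argued against by the rest of X. There the median relative log2 ratio was -0.0406 (bootstrap 95% range -0.06 to -0.02), against -0.57 in the segment. That range is wholly negative, so a small drop over the whole of X stays open. The relative log2 ratio is centred on the pairs of the whole library, so it cannot test a library-wide difference. Over all pairs the median Tle4cKO to WT pileup ratio was 0.741. The rest of X also had few Tle4cKO-only peaks, 8.0%, so that their scarcity in the segment stays open. Changes of separate elements stay open, since the spread of the ratio in the segment, 1.12 times (0.993 to 1.24) that of pairs of like pileup outside X, was set against a bound chosen after the spread was seen, in bins chosen for low medians. A difference in copy number of the segment between the 2 pools stays open as well, without support, because the share of pairs below, 94.5%, restates the low ratios for which the segment was chosen. An effect of the genotype on the segment stays open too and was untested, since each genotype has 1 pool.

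Strong peaks missing from the other list stay undecided. If they were mainly pieces of regions that 1 list splits, at least 50% would lie within 500 bp of a peak of the other list, and under 20% if not; 35.2% (29.7% to 41.1%) did. A local difference in accessibility predicted more distant strong peaks than Poisson thinning gives, and 175 were found, but thinning removed 0 strong peaks in 100 draws, so that any count would have passed and the test decides nothing. Whether a peak of 1 list is missing from the other through the calling step or through a lack of reads cannot be told apart without the reads.

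Tle4cKO-only peaks gathered at 40 to 42 Mb of chromosome 19, where 24 of 177 Tle4cKO peaks of pileup 15 or more were Tle4cKO-only (13.6%, against 3.3% over the genome). With 10 kb on either side and all pileups counted, Pik3ap1, an adaptor of PI3-kinase signalling, held 11 Tle4cKO-only and 8 WT-only peaks, the highest of pileup 36 and 56, and Entpd1, which encodes the ectonucleotidase CD39, held 10 and 4, the highest of 35 and 50. Of the WT peaks of pileup 15 or more in the window, 23 of 189 were WT-only (12.2%, against 10.9% over the genome). A gain in copy number of the window is argued against by its 175 pairs, whose median relative log2 ratio was -0.0226 (-0.06 to 0). Splitting of regions stays open, since 29.2% (14.9% to 49.2%) of the 24 peaks lay within 500 bp of a WT peak, between the bounds of 20% and 50%. An untested genotype effect stays open as well. The window was not alone in its share of Tle4cKO-only peaks at that pileup. At 52 to 54 Mb of chromosome 4 it was 12 of 96 (12.5%), and at 30 to 32 Mb of chromosome 6 it was 15 of 157 (9.55%).

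Outside the distal segment, 160 of 2000 Tle4cKO peaks on X were Tle4cKO-only (8.0%, against 23.7% elsewhere in the genome), and 722 of 2471 WT peaks on X were WT-only (29.2%, against 27.0%). Of all Tle4cKO peaks outside the segment, X held 0.848% of those of pileup 10 or less and 1.78% of those of pileup 20 to 50, against 1.48% and 2.08% in WT. Since most list-only peaks are weak, the low share of Tle4cKO-only peaks on X goes with a scarcity of weak Tle4cKO peaks there, the cause of which was not tested.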
